A study of Homo sapiens with 28 samples.

How the data were processed

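Reduced representation bisulfite sequencing (RRBS) reads the methylation of cytosines in the CpG-rich part of the genome: genomic DNA is cut at CpG-containing sites, short fragments are treated with bisulfite, which converts unmethylated cytosines, and the share of reads that keep a C at a position is its methylation level. The assay was run on genomic DNA from 28 established human breast cancer cell lines, with 1 library per line. The deposited table gives the methylation level in percent, as whole numbers from 0 to 100, at 479745 cytosine positions for each of the 28 lines, and the authors' unit was taken as it stands. Reads were aligned with Bowtie to hg19, per the submitters' processing notes. The Bowtie version, the caller and any read minimum are not given in the sources used here. The table gives no read counts, so the depth behind each value is unknown, and no interval or detection limit that needs it was computed. It holds positions with a value in at least 26 of the 28 lines: 305071 had a value in every line, 109345 lacked 1 line and 65329 lacked 2. All column names matched the name of 1 line, and 0 columns of per-sample values were left unmatched.

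Each entry is a cytosine position, so the same CpG can appear once per strand. At 50029 autosomal places the next position lay 1 bp further on, and the values of such pairs give an empirical idea of the precision per value. Pairs with a mean of at most 5% differed by 1.43 points on average, pairs between 20% and 80% by 9.84 points, and pairs above 95% by 2.67 points. The largest position on every chromosome lay within the hg19 length, and on 14 chromosomes it lay beyond the end of the hg38 sequence. The gene annotation at hand was of hg38 and was not applied to these positions, coordinates were not converted, and regions are given by hg19 chromosome, start and end (counted from 1) and by the hg19 cytogenetic band table of the R package circlize 0.4.16. No gene names are attached to regions for this reason, and the planned comparisons of gene promoters and gene lists were not run.

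The labels name each line without its subtype, while the design text counts 18 basal-like and 10 luminal lines. Lines were placed by the established class of the named line, with mesenchymal basal lines counted as basal-like: 18 were basal-like and 9 luminal. The basal-like lines were 2LMP, BT-20, BT-549, HCC1143, HCC1187, HCC1569, HCC1599, HCC1937, HCC1954, HCC38, HCC70, MDA-MB-157, MDA-MB-231, MDA-MB-436, MDA-MB-468, SUM102, SUM149 and SUM159. The luminal lines were BT-474, MCF-7, MDA-MB-134, MDA-MB-361, MDA-MB-453, SK-BR-3, T-47D, ZR-75-1 and ZR-75-30. DY36T2 was left without a group, enters no comparison between groups, and is given as values only. The line is the replicate, and p-values measure the spread between lines. 2LMP is derived from MDA-MB-231, so these lines share a tumour of origin. The labels give different growth media for different lines and no sequencing batch or date.

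Tests used the autosomes. A position was tested with values in at least 14 basal-like and 7 luminal lines, which left 471625 positions. Positions at most 200 bp from the next were joined into clusters, and the mean level per line was taken over each cluster of at least 3 positions (39895 clusters). Levels in percentage points were compared with limma 3.58.1 in R 4.3.3 (moderated test, variance trend with the mean level, two-sided) and adjusted by the Benjamini-Hochberg method over all positions or all clusters. A position or cluster was called at an adjusted p below 0.05 and a difference of group means of at least 25 points. Named regions are the 10 called clusters with the largest difference in each direction among those of at least 5 positions. This rule, the thresholds and the tests were fixed before the data were examined. For the named regions and for mean levels, an exact permutation test over all 4686825 splits of the 27 lines was run as well (two-sided). At 10q26.3, where MDA-MB-157 had no value, the splits were those of the remaining lines. Group means and tests of the mean level per line used the 302180 autosomal positions with values in all 27 lines. Mean levels given for single lines used the 300948 with values in all 28 lines. Positions in clusters of at least 10 positions are called dense and all others sparse. This class counts measured positions, both strands of a CpG included, so it only stands in for CpG density. Similarity between lines was Pearson's r over 300948 autosomal positions with values in all 28 lines, and the mean r within groups minus the mean r between groups was tested with 100000 permutations of the group labels (one-sided, towards higher values). Chromosomes were compared with Fisher's exact test, adjusted over the 22 autosomes.

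The code was tested on simulated data made from the real values with 200 altered features. The values of each feature were shuffled over the lines separately, which removes the correlation between features. The same shift was then added to every basal-like line, at features with a low or high mean level. The recovery and false calls therefore check the code and do not give the rates in the real data. At the level of clusters (39895 features), 73% of differences of 30 points and 95% of those of 60 points were recovered, with 7 false calls. At the level of positions (471625 features) the shares were 53% and 93%, with 5 false calls. Alternatives tried were M values, values required in all 27 lines, other minimum differences, levels centred per line, other variance models, the inclusion of chromosome X, other cluster definitions, the omission of 2LMP or of the HER2-amplified basal-like lines HCC1569 and HCC1954 (luminal lines with HER2 amplification, such as BT-474 and SK-BR-3, were kept, so HER2 status was not balanced between the groups), and, added after seeing the data, merged strands and the omission of each line in turn. Data were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9.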

Results

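DNA methylation was measured by RRBS in 28 breast cancer cell lines, of which 18 were basal-like and 9 luminal, with 1 line (DY36T2) left without a group. Basal-like lines mostly lack the oestrogen receptor, and many express genes of the basal layer of the mammary epithelium. Luminal lines, such as MCF-7 and T-47D, express genes of the hormone-responsive luminal layer. The basal-like group here includes mesenchymal basal lines, which were not compared separately, so it is not a single uniform class. The study set out to find regulatory regions particular to basal-like breast cancer, and the comparison of interest is basal-like against luminal lines. Values were methylation levels in percent at 479745 positions, of which 471625 lay on autosomes, 8029 on chromosome X, 84 on chromosome Y and 7 on the mitochondrial genome. Between 443018 (ZR-75-30) and 479123 (SUM102) positions had a value in a line. The read depth behind each level is unknown.

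The first question was whether the subtypes differ in their methylation as a whole. They did not differ detectably: the mean level per line was 24.5% ± 4.50 (SD, n = 18) in basal-like lines and 25.1% ± 4.56 (SD, n = 9) in luminal lines (exact permutation test, p = 0.73, adjusted p = 0.821 over 3 sets of positions). The spread within each group was far wider than this difference. Over the autosomal positions with values in all 28 lines, the mean of single basal-like lines ran from 16.2% in HCC70 to 33.8% in 2LMP. Among luminal lines it ran from 15.3% in SK-BR-3 to 31.3% in MDA-MB-453. At dense positions, which lie in clusters of at least 10 measured positions, basal-like lines averaged 10.7% ± 4.28 (SD, n = 18) and luminal lines 11.1% ± 3.31 (SD, n = 9), with an exact permutation p of 0.821. At sparse positions the levels were 48.8% ± 5.85 (SD, n = 18) and 49.9% ± 7.72 (SD, n = 9), with an exact permutation p of 0.68.

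**Figure D1:**
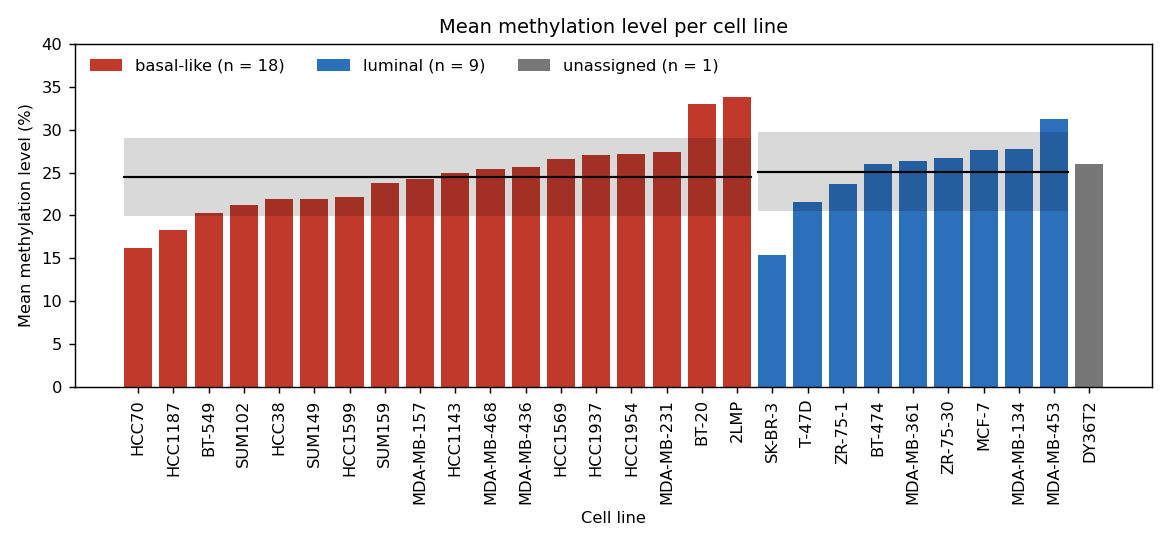
Mean methylation level (%) of each cell line over the 300948 autosomal positions with values in all 28 lines, as bars from 0, coloured by group. Black lines and grey bands give the mean ± SD of each group over the positions measured in all 27 grouped lines, 24.5% ± 4.50 for basal-like and 25.1% ± 4.56 for luminal lines.

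Individual regions did differ in group mean between the subtypes, although the groups overlapped at most of them. Of 39895 CpG clusters, 407 were called, 218 with higher and 189 with lower methylation in basal-like lines. Clusters lower in basal-like lines had a median level of 12.1% in those lines and 67.8% in luminal lines, and 127 of the 189 averaged below 20% in the basal-like group. Clusters higher in basal-like lines had a median of 84.3% there against 34.2% in luminal lines, and 135 of the 218 averaged above 80% in the basal-like group. At the level of single positions, 2299 of 471625 were called, 1170 higher and 1129 lower in basal-like lines. Without the minimum difference, 502 clusters and 2477 positions passed the adjusted threshold in limma. When positions with any missing line were left out, 223 clusters and 1402 positions were called. Clusters of at least 5 positions gave 142 calls, 59 higher and 83 lower in basal-like lines. The balance of directions rested on single lines: without SK-BR-3, 170 clusters were higher and 260 lower in basal-like lines.

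Among called clusters of at least 5 positions with lower methylation in basal-like lines, the largest difference lay at 2q23.3 (chromosome 2, 153192737 to 153192830, 6 positions). Its level was 1.73% ± 1.76 (SD, n = 18) in basal-like and 83.3% ± 12.3 (SD, n = 9) in luminal lines, a difference of -81.6 points (SE 4.91, limma adjusted p = 2.11e-11), and no basal-like line exceeded 7.17% while no luminal line fell below 63.5%. The region at 7q31.2 (chromosome 7, 116140038 to 116140334, 7 positions) was likewise nearly free of methylation in every basal-like line (at most 3.71%), at 1.53% ± 1.02 (SD, n = 18), against 67.8% ± 17.7 (SD, n = 9) in luminal lines (limma adjusted p = 9.07e-10). For these regions the exact permutation p of 2.13e-07 is the smallest the 4686825 splits can give. At 12q12 (chromosome 12, 39298733 to 39299009, 6 positions) the levels were 5.99% ± 11.4 (SD, n = 18) and 70.4% ± 25.7 (SD, n = 9), with a limma adjusted p of 1.01e-05, and 2 basal-like lines reached the luminal range.

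At the other named regions with lower levels in basal-like lines, some basal-like lines reached the luminal range. A basal-like line was counted when it lay at or above the lowest luminal line. Such lines numbered 2 of 18 at 2p21, 3 at each of 3q29, 11q24.1, 7q33 and 2q13, 6 at 11p15.1 and 12 at 3p22.3. A single low luminal line set the count at 11p15.1 (SK-BR-3, 24.9%) and at 3p22.3 (T-47D, 0.667%). Below 50% were 15 of the 18 basal-like lines at 11p15.1 and 16 at 3p22.3. The cluster at 2p21 (chromosome 2, 43019975 to 43019997, 5 positions) averaged 95.7% ± 3.42 (SD, n = 9) in luminal lines and 25% ± 33.5 (SD, n = 18) in basal-like lines, where single lines ran from 0.4% to 98%. The cluster at 3q29 (chromosome 3, 193587451 to 193587691, 15 positions) had 96.5% ± 1.30 (SD, n = 9) and 29.7% ± 36.5 (SD, n = 18), and its highest basal-like line reached 97%. At 11p15.1 (chromosome 11, 16626091 to 16626127), 11q24.1 (chromosome 11, 123301316 to 123301361), 7q33 (chromosome 7, 134143587 to 134143715) and 2q13 (chromosome 2, 110873030 to 110873164) the differences were -65.4, -62.6, -61.7 and -61.6 points. SK-BR-3 stood below the other luminal lines at 11p15.1, with 24.9%, and at 2q13, with 50.3%. At 3p22.3 (chromosome 3, 32433687 to 32433807, 12 positions) the difference was -63.3 points (SE 13.8, limma adjusted p = 0.0144), and each group held lines near both ends, from 0.0833% to 98.6% among basal-like and from 0.667% to 97.9% among luminal lines.

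Among called clusters of at least 5 positions with higher methylation in basal-like lines, the largest difference lay at 16q24.1 (chromosome 16, 85741413 to 85741548, 5 positions), with 83.4% ± 25.02 (SD, n = 18) in basal-like and 5.09% ± 4.85 (SD, n = 9) in luminal lines. The difference was 78.3 points (SE 8.78, limma adjusted p = 2.75e-06), and 1 basal-like line, MDA-MB-468 at 9.8%, lay below the highest luminal line at 14%. At 14q32.12 (chromosome 14, 93483956 to 93484001, 5 positions) the levels were 78.2% ± 24.8 (SD, n = 18) and 8.36% ± 10.9 (SD, n = 9), and at 19p13.2 (chromosome 19, 7685153 to 7685239, 6 positions) they were 74.6% ± 30.7 (SD, n = 18) and 7.02% ± 9.51 (SD, n = 9). The cluster at 17p13.3 (chromosome 17, 1901318 to 1901593, 12 positions) did not exceed 7.75% in any luminal line, with 2.42% ± 2.43 (SD, n = 9), and averaged 65.7% ± 30.9 (SD, n = 18) in basal-like lines, of which HCC70, at 3.75%, lay within the luminal range. A pair of neighbouring clusters at 14q21.1 (chromosome 14, 38061183 to 38061303 and 38061819 to 38061984) differed by 65.7 and 63.8 points, and the highest luminal line, MCF-7 in each, had 29.4% and 29.0%. In each of them 5 of 18 basal-like lines lay below MCF-7, down to 0% and 1%. At 1p36.22 (chromosome 1, 9399057 to 9399306, 5 positions) basal-like lines had 84.9% ± 12.7 (SD, n = 18), from 47% in MDA-MB-468 to 96.6%, against 28.0% ± 11.2 (SD, n = 9) in luminal lines (limma adjusted p = 6.7e-08). The remaining named regions at 10q26.3 (chromosome 10, 134209485 to 134209512), 2q36.3 (chromosome 2, 227665839 to 227665973) and 15q24.1 (chromosome 15, 74537972 to 74538030) differed by 65.9, 63.8 and 56.5 points. At 10q26.3, 17 basal-like lines had a value. Basal-like lines at or below the highest luminal line numbered from 1 to 5 at each of the 10 regions. At 2q36.3 and 10q26.3 a single luminal line stood above the others, BT-474 at 63.7% and MCF-7 at 36%. Across the 20 named regions the limma adjusted p was at most 0.0144.

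**Figure D2:**
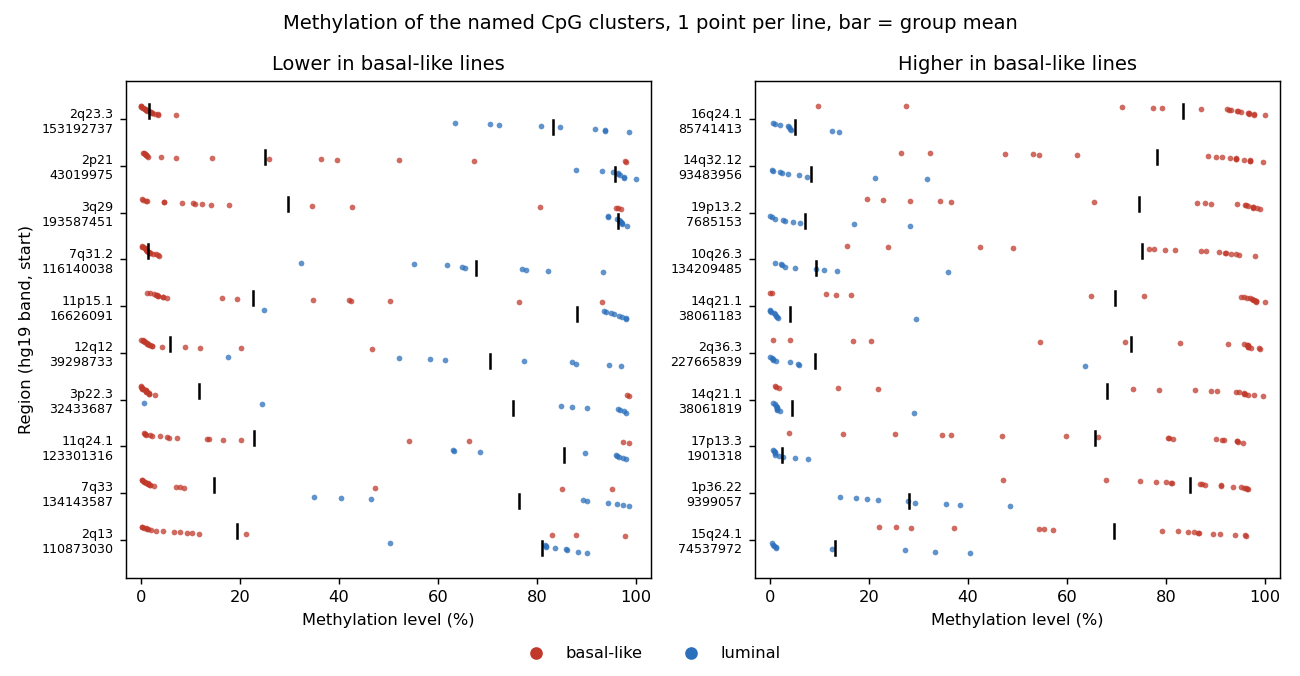
Methylation level (%) of the 20 named clusters, 10 lower (left) and 10 higher (right) in basal-like lines, with 1 point per line (red basal-like, blue luminal) and a black bar at each group mean. At 2q23.3 every basal-like line lies at or below 7.17% and every luminal line at or above 63.5%, whereas at 3p22.3 lines of each group lie near both ends.

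In 24 of the 407 called clusters the groups did not overlap, 9 with lower and 15 with higher levels in basal-like lines. The gap between the closest lines of the groups exceeded the mean strand difference at that level in 11 of the 24 and lay within it in the other 13. The gap is between cluster means and the strand difference between single positions, so the comparison is only a rough guide to precision. By chance, a cluster with values in all 27 lines has complete separation in 1 given direction in 1 of the 4686825 splits. Clusters that lack a line have fewer splits. The examples given here were chosen after their values were seen, and most have fewer positions than the named rule asks for. At 17p12 (chromosome 17, 15849097 to 15849120, 4 positions) the levels were 5.0% ± 16.4 (SD, n = 18) in basal-like and 93.4% ± 8.75 (SD, n = 9) in luminal lines, although the closest lines of the groups, at 70.5% and 70.8%, lay within the strand difference. At 1p36.12 (chromosome 1, 21877549 to 21877583, 4 positions) they were 90.4% ± 12.2 (SD, n = 18) and 4.64% ± 3.83 (SD, n = 9), and at 20q11.21 (chromosome 20, 31097656 to 31097713, 3 positions) 81.6% ± 16.4 (SD, n = 18) and 1.26% ± 0.683 (SD, n = 9). At 9q34.2, clusters at 137251210 to 137251326 and at 137259443 to 137259466 had 69.2 and 57.4 points more in basal-like lines, with a gap of 37.5 points between the closest lines at the first and of 2 points, within the strand difference, at the second. A longer cluster at 6p25.3 (chromosome 6, 1611720 to 1611967, 12 positions) was unmethylated in all basal-like lines, at 1.22% ± 0.570 (SD, n = 18), while luminal lines ran from 2.67% to 99.3%. Its highest basal-like line, at 2.5%, lay closer to the lowest luminal line than the mean strand difference of 1.43 points at low levels.

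The map of the region at 2q23.3 shows where the difference began. Over 41 measured positions from 153191531 to 153192830, those outside the called cluster differed by at most 15.6 points between the group means. Luminal lines averaged 10.8% ± 13.95 (SD, n = 9) at position 153192477 and 16.6% ± 17.2 (SD, n = 9) at 153192515, between the unmethylated stretch and the called cluster. Within 2000 bp of the 16q24.1 cluster no position outside the cluster was in the table.

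**Figure D3:**
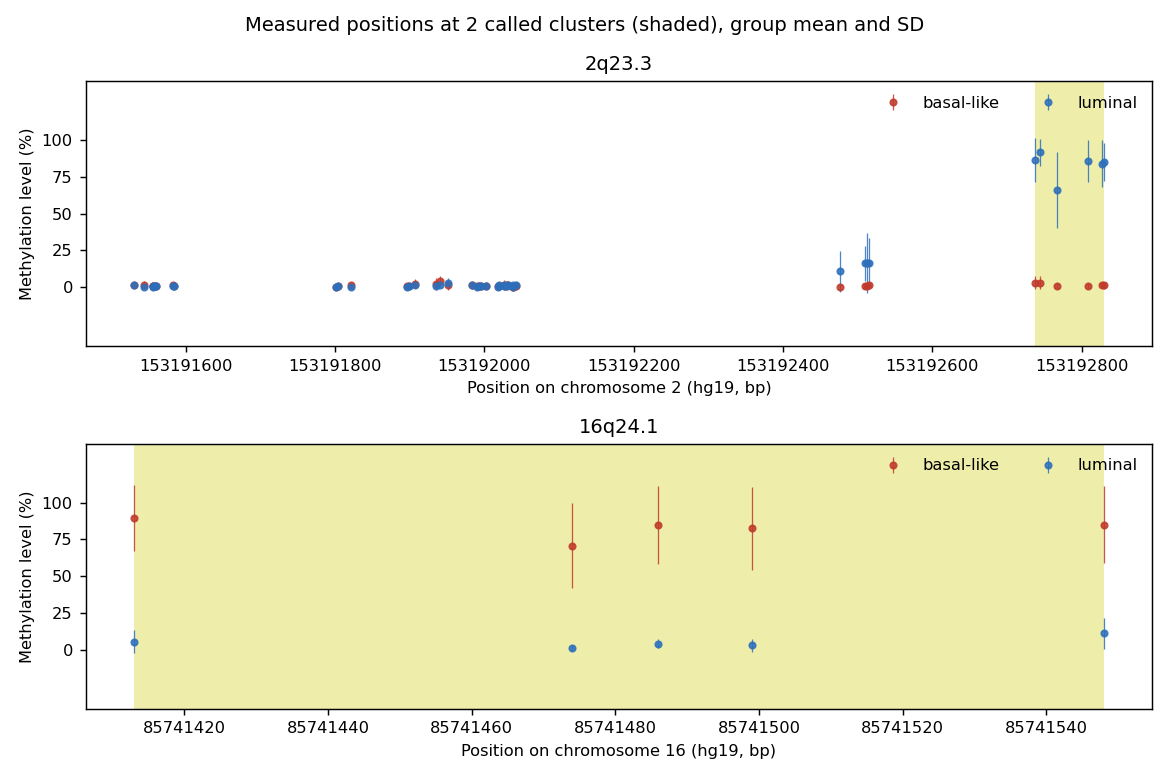
Methylation level (%) against hg19 position (bp) for the measured positions within 2000 bp of the called clusters at 2q23.3 and 16q24.1 (shaded), as group mean with SD bars (18 basal-like lines in red, 9 luminal lines in blue). At 2q23.3 both groups lie near 0 over most positions and part in the shaded cluster, and at 16q24.1 all 5 positions are higher in basal-like lines.

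Called positions were then compared by CpG density and by chromosome, in place of gene position. Of 292938 dense positions, 638 (0.218%) were called, and 495 of these (77.6%) were lower in basal-like lines. Of 178687 sparse positions, 1661 (0.930%) were called, and 634 of these (38.2%) were lower. The gap between dense and sparse positions in the share that was lower did not stand out from random groupings: over the 2299 positions of lowest p it was 41.7 points, and 28 of 100 splits of the lines, the real one included, gave a gap as large. By chromosome, no autosome passed adjustment over the 22 for the share of clusters called (lowest Fisher's exact adjusted p = 0.11, chromosome 11, 35 of 2106 clusters) or for direction. The lowest adjusted p for direction was 0.079, for chromosome 3, where 17 of 22 called clusters were lower in basal-like lines. Bands with the most called clusters were 17q25.3 with 12 (8 higher and 4 lower in basal-like lines), 16q24.1 with 9 (8 higher and 1 lower) and 11p15.5 with 8 (7 higher and 1 lower). Among bands with at least 4 called clusters, all were higher in basal-like lines at 16p13.3 (6 clusters), 10p15.1, 11q13.4 and 17p11.2 (4 each), and all were lower at 3p22.3 and 7p15.3 (4 each). These band counts were not tested. On chromosome X, 4 of 891 clusters were called, 2 in each direction.

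The last question was whether the lines resemble each other by subtype. Over all positions, the mean correlation across positions was 0.790 (SD 0.0523 over pairs) between basal-like lines, 0.812 (SD 0.0622) between luminal lines and 0.778 (SD 0.0494) between the groups. Pairs within a group exceeded pairs between groups by 0.0161 (one-sided permutation test, p = 0.039), a difference smaller than the SD over pairs. With Spearman's rho the excess was 0.00963 (permutation p = 0.11), and the call was also lost when any 1 of 8 lines was left out: SUM149 (p = 0.054), MCF-7 (0.065), MDA-MB-134 (0.065), MDA-MB-361 (0.059), MDA-MB-453 (0.12), SK-BR-3 (0.088), T-47D (0.085) or ZR-75-30 (0.061). The subtypes parted more clearly over the 20000 most variable positions, where the mean r was 0.120 between basal-like lines, 0.253 between luminal lines and 0.0141 between the groups (permutation p = 1e-05, the smallest the permutations can give). Among grouped lines the closest pair was BT-474 and ZR-75-1, both luminal (r = 0.896). 2LMP was closest to MDA-MB-231, the line from which it derives (r = 0.869). SK-BR-3 had its highest correlation with a basal-like line, HCC70 (r = 0.797). These lines had the lowest mean levels of their groups, 15.3% and 16.2%, and a link with their correlation was not tested. The mean r of SK-BR-3 was 0.721 with the other luminal lines and 0.725 with basal-like lines. A higher mean r with the other group was also found for the basal-like lines BT-20 (0.763 with basal-like and 0.787 with luminal lines) and HCC1954 (0.801 and 0.822). Positions are not independent replicates, and these correlations describe pairs of libraries.

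**Figure D4:**
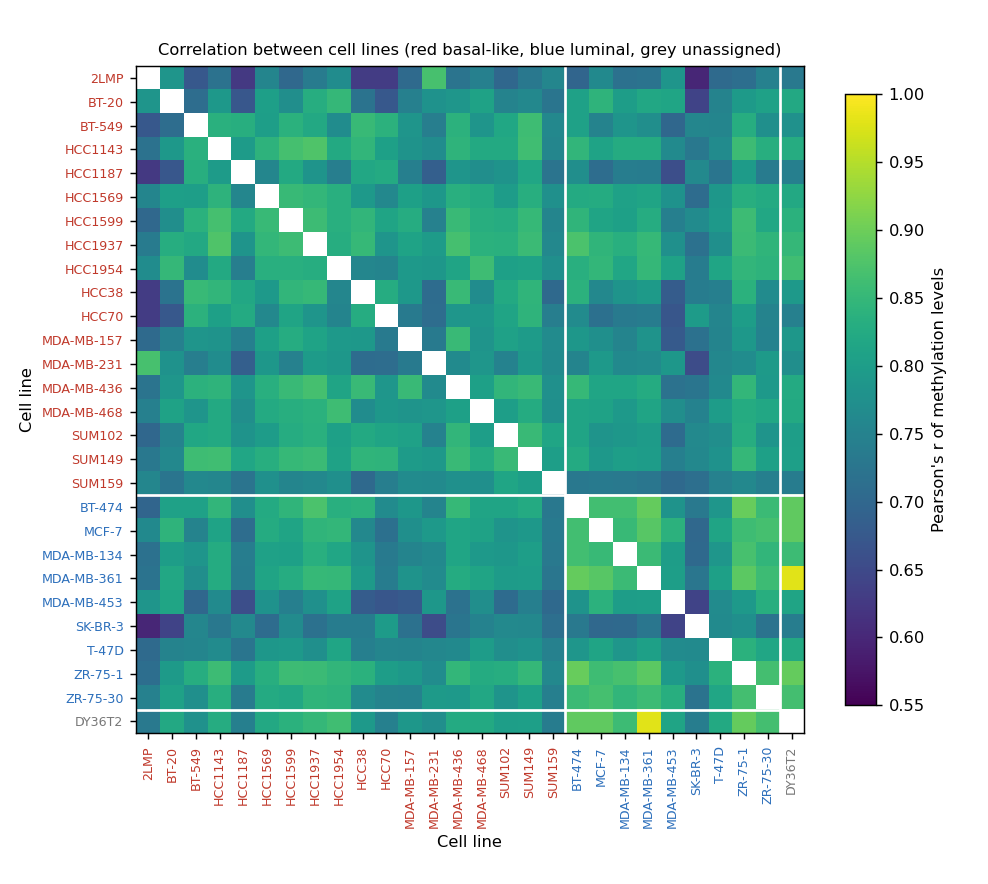
Pearson's r of methylation levels over 300948 positions for every pair of the 28 lines (colour scale), with basal-like lines in red, luminal lines in blue and the unassigned line in grey, and white lines between groups. Basal-like and luminal blocks are only slightly brighter than the pairs between groups, and the brightest cell is MDA-MB-361 with DY36T2 (0.979).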

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

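The tests by CpG density described here were chosen after the results were seen, whereas those on the number of calls were fixed beforehand. A luminal line was marked when its gap to the nearest other luminal line exceeded Dixon's limit for 9 lines. Of 24 groups of values looked at, 7 had such a line. The limit marks about 1 group in 20 by chance only when values are independent and normally distributed. Most groups here were bounded percent levels at regions picked for large subtype differences. The neighbouring clusters at 14q21.1 marked the same line, MCF-7. The count of 7 in 24 therefore cannot show an excess of such lines. The basal-like group is too large for this rule.

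MCF-7 stood above the other luminal lines at 3 named regions. At 14q21.1 it had 29.4% in the cluster at 38061183, where the next luminal line had 1.6%, and 29% in the cluster at 38061819, where the next had 2%. At 10q26.3 (134209485) it had 36%, above 13.5% in the next line. BT-474 had 63.7% at 2q36.3 (227665839), and the next luminal line had 5.8%. SK-BR-3 stood apart in the other direction at regions methylated in luminal lines, with 24.9% at 11p15.1 (16626091) against 93.5% in the next line and 50.3% at 2q13 (110873030) against 81.7%. At positions whose median level over lines was at most 1%, MDA-MB-453 averaged 3.44%, the highest luminal value, followed by 2.14%. No explanation was tested for these values.

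The number of regions called between the subtypes was weighed against 3 technical or statistical explanations. Chance is argued against for it, though not excluded. In 100 splits of the 27 lines into groups of 18 and 9, only the real one gave as many called positions, 2299 against 636 in the highest other split. Only the real one gave as many called clusters, 407 against 188. In that highest other split 5 of the 9 lines of the small group were luminal. With 100 splits, a share below 1 in 100 cannot be seen. Before adjustment, 4803 clusters had a limma p below 0.05 in the real split, and some other splits had more, up to 8475. A different overall level of the libraries in 1 group is argued against by the mean levels, which differed by -0.645 points (basal-like minus luminal). Subtracting each line's mean could therefore move the group differences only slightly and was a weak test. After it, 98.28% of the called clusters were still called. Without 2LMP, the tumour it shares with MDA-MB-231 counts once, and 398 clusters were called. The number of calls therefore does not need that tumour to be counted as 2 lines. Of the 407 called clusters 88.45% were still called, a share that cannot decide more. Omitting any 1 line kept most of them, from 295 (without MDA-MB-361) to 380 (without BT-20). What stays open, untested, is the subtype itself and anything that goes with it in these cultures, such as growth medium or HER2 status.

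The direction of the difference by CpG density, with 77.6% of called dense positions but 38.2% of called sparse positions lower in basal-like lines, was weighed in the same way. A general offset of dense or sparse positions in 1 group is argued against by the mean levels. Basal-like minus luminal was -0.378 points at dense and -1.12 points at sparse positions. Removing each line's mean over positions of the same density could therefore change little, and the gap between the shares stayed at 38.18 points. Chance cannot be excluded for the gap: 28 of 100 splits gave a gap as large over the 2299 positions of lowest p (41.7 points for the real groups, 71.8 in the highest other split), and 34 of 100 did over the 26289 positions that differ by at least 25 points. The density pattern may therefore be one that groupings of these lines can give without regard to subtype.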

How the results depend on the processing

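Merged strands, the omission of each line in turn, centring within density class and M values for the density split were chosen after seeing the data. Requiring values in all 27 lines gave 1402 positions (728 higher and 674 lower in basal-like lines) and 223 clusters (117 higher and 106 lower), with fewer positions tested. Clusters of at least 5 positions gave 142 calls (59 higher and 83 lower), with fewer clusters tested. Under the other settings the calls stayed within 1.5 times the reported 2299 positions and 407 clusters: 2758 and 529 with M values, 2775 and 516 with centred levels, 2720 and 429 with a robust variance model, 1961 and 301 with a minimum of 40 points, and 2196 and 398 without 2LMP. Leaving out each line in turn gave from 306 (without MDA-MB-361) to 454 (without BT-20) clusters. The balance of 218 higher and 189 lower clusters turned to 170 and 260 without SK-BR-3, 212 and 242 without BT-20, 193 and 205 without 2LMP, 189 and 205 without HCC1569 and HCC1954, and 147 and 154 with a minimum of 40 points. For positions, 1170 higher and 1129 lower turned to 1316 and 1442 with M values, 1241 and 1479 with a robust variance model, 1235 and 1471 without the variance trend, 920 and 1041 with a minimum of 40 points, 1052 and 1144 without 2LMP, and 1023 and 1185 without HCC1569 and HCC1954. Which direction holds more calls is therefore not settled. All 20 named regions kept their direction and their call in each alternative that gave a value for them, and 16 had one when values in all 27 lines were required. They were picked for the largest differences in the same data, so keeping the call was likely from the start. Apart from 2LMP, the omission of each line in turn was not run for the named regions. The mean level per line stayed without a detectable difference in every alternative run. The excess similarity within subtypes lost its call with Spearman's rho, at 0.00963 (p = 0.11). It ranged from 0.0117 (without MDA-MB-453, p = 0.12) to 0.0198 (without BT-20, p = 0.016) over the lines left out, with p at or above 0.05 in 8 of 27 cases; the cause was not tested. The share of called positions lower in basal-like lines ran from 74.5% to 80.3% at dense and from 40.2% to 42.8% at sparse positions over the alternatives. The promoter and gene list comparisons with their alternatives, the split by gene position, and the coverage minimum and read-based test were not run, since they need a gene annotation of hg19 or read counts. Depth per value is unknown, so small differences at intermediate levels cannot be weighed against counting error.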

Other observations

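Many clusters ranged widely over the lines. Of 35167 clusters with values in all 28 lines, 12589 had at least 80 points between the lowest and the highest line, and 321 of these (2.55%) were called between the subtypes. At the other extreme, 10967 clusters were below 10% in every line and 1379 were above 90% in every line.

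Methylation states held by a single line were spread unevenly. Clusters in which 1 line stood at least 30 points above all others numbered 1441, of which 363 belonged to 2LMP, 232 to MDA-MB-453, 166 to BT-20 and 113 to MDA-MB-134. Clusters in which 1 line stood at least 30 points below all others numbered 1197, of which 471 belonged to SK-BR-3, 226 to HCC1187 and 106 to HCC70. The lines with many private losses were those with the lowest mean levels (15.3%, 18.3% and 16.2%), and 2LMP and BT-20 had the highest (33.8% and 33.0%).

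2LMP and its parent line MDA-MB-231 differed mostly in 1 direction. Of 35167 clusters, 2360 were at least 40 points higher and 291 at least 40 points lower in 2LMP, and 11 of the 378 pairs of lines differed at fewer clusters. Of 18152 clusters below 20% in MDA-MB-231, 1115 were above 60% in 2LMP, and of 10351 clusters above 80% in MDA-MB-231, 104 were below 40% in 2LMP. 2LMP also had the highest level at positions that are nearly unmethylated across lines (6.51%, against 3.00% in MDA-MB-231), while its mitochondrial positions, which are read as unmethylated in these lines, averaged 1.29%, against 0.286% in MDA-MB-231 and 2.29% in MDA-MB-436, the highest of all lines. Each line has 1 library, and no test was made.

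DY36T2, the line without a group, had a mean level of 26.04%. Its correlation with MDA-MB-361 was 0.979, the highest of the 378 pairs, and 68 clusters were at least 40 points higher and 50 at least 40 points lower in DY36T2, against a median of 4334 clusters over all pairs. Its mean correlation was 0.861 with luminal and 0.798 with basal-like lines.

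Called clusters seldom lay in long runs. With at most 20000 bp between starts, 3 runs of at least 3 called clusters of the same direction were found, all higher in basal-like lines: 6p21.31 (chromosome 6, 34507140 to 34521718), 16q24.1 (chromosome 16, 85470362 to 85483026) and 17p13.3 (chromosome 17, 708409 to 729530). At 6p21.31 the differences ran from 45.6 to 75.4 points.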
